A study of Mus musculus with 2 samples.

How the data were processed

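The series holds 2 libraries of mouse marrow stromal cells, 1 pulse and 1 chase, made with the 10x Genomics Single Cell 3 prime kit version 3.1 per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, which the authors did not normalise; the values are whole numbers. Cell Ranger version 6.0.2 made the counts per the file headers, whereas the submitters' processing notes name version 2.1.1, and this difference could not be settled. The processing notes give the genome build as mm10; the annotation release is not given in the sources used here. A tdTomato entry is among the 32286 features. The barcodes are a set already called as cells, since the lowest total is 500 UMIs in both libraries and the highest 60307 and 68403. Gene positions were taken from the GENCODE vM21 annotation of the same build by Ensembl identifier and count from 1. Groups follow the labels' harvest time.

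Cells were kept with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs, which passed 9390 of 10608 pulse barcodes (88.5%) and 8445 of 10046 chase barcodes (84.1%). Scrublet, as written in scanpy 1.11.5, was run per library with its automatic threshold and removed 178 pulse cells (1.90%) and 110 chase cells (1.30%). A loading rate of 0.8% per 1000 barcodes would have removed 797 and 679, so doublets are likely to remain in the kept cells, and this removal was run as an alternative. Exact neighbours were used in Scrublet after the approximate search had marked under 0.5% of the pulse cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and both libraries were clustered jointly without integration (15 neighbours, Leiden at resolution 1, seed 1; leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0).

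Clusters were named from markers of 21 cell types fixed in advance, of which 1 marker was not found by name. A marker counted when it had at least 20 CPM (UMIs scaled to the total of the cluster or class) in the cluster and lay at least 2-fold above the unweighted mean of the other clusters (pseudocount 5 CPM), and a name needed at least 3. The type with the highest mean log2 excess was taken. The rest of the rule was tuned on these data. A name also needed a mean log2 excess of at least 1. A type of the same compartment took the name if it reached 60% of the best score and had more markers among the 10 leading genes. A cluster in which a type of another compartment had 3 such markers and reached 50% of the score stayed unnamed. No name was given where another type had more markers among the 10 leading genes (at least 50 CPM), or where the median depth was under the library median divided by 3 with no own marker leading. A cluster with none of its own markers among its leading genes that shared at least 5 of them with a larger cluster of another class also stayed unnamed. Earlier forms used 60% (first rule, with neither the minimum excess nor the step within a compartment) and 40% (second rule), and both were run as alternatives. Stromal cells are the CAR, osteoblast, osteocyte, chondrocyte, fibroblast and mature adipocyte classes, and blood-like cells are 10 classes from neutrophil to progenitor.

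Shares carry exact (Clopper-Pearson) 95% binomial intervals, summed counts exact Poisson intervals, and ratios of counts an exact interval conditional on the total. All of these cover counting error only, since cells are not replicates and 1 library per group gives no test. A count of 0 is set against the level that 3 counts would give. For gated shares each cell was thinned at random to 2000 UMIs and counted with at least 1 UMI; a deeper thinning to 8000 UMIs with at least 5 UMIs was added for the reporter after the data were seen. UMIs were summed per library and class and divided by the class total. Genes with at least 50 UMIs over both libraries were described. A list member was counted as higher or lower when its ratio reached 1.5-fold and its interval excluded 1. Log2 ratios carry a prior count of 0.5 per gene. Each list has its median log2 ratio, a counting interval from 1000 Poisson draws, and its percentile among 10000 random lists of the same size drawn from 20 expression bins, which describes these libraries and tests nothing. Osteoblast-like cells were compared because each library held at least 50 of them.

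Named genes in CAR-like cells are the 12 highest and 12 lowest chase-to-pulse ratios among genes with at least 50 CPM in the higher library. Mitochondrial, ribosomal protein and predicted genes and blood markers were left out. The same rule took 8 and 8 in osteoblast-like cells. From each list up to 3 members with the largest absolute log2 ratio and at least 20 CPM were eligible as examples, of which 2 are not reported here. Adipoq, Lepr, Cxcl12, Kitl, Lpl, Pparg, Cebpa, Alpl, Wif1, Sp7, Runx2, Spp1, Bglap and Col1a1 were always named. The tdTomato reporter was added to these after the data were seen. The filters, the markers, the 17 gene lists, the naming of genes and most alternatives were chosen before the data were examined. Of the list members, 4 were not found by name. Another 4 lists (clock output, clock activator, glucocorticoid-induced and contractile genes) were added afterwards and are used only in the closing section.

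Alternatives covered the cell filter (none, or at least 1000 genes and under 5% mitochondrial UMIs), doublets kept, resolutions 0.5 and 2, libraries clustered separately, thinning to 1000 or 4000 UMIs or none, at least 2 UMIs per gene, TMM scaling (edgeR 4.0.16), median of ratios (DESeq2 1.42.0, both in R 4.3.3), mean of per-cell CPM, no low-count filter, and adipogenic CAR-like clusters alone. Under the strict filter Scrublet marked 0.0673% of pulse cells, so the loading rate removed 630 there (8.48%). The automatic call removed 72 chase cells (1.12%), so that setting also changed the doublet removal, unequally between the libraries. Alternatives added after the data were seen were doublets at the loading rate, the earlier naming rules, clustering without the differing genes, and all alternatives for osteoblast-like cells. Ratios, intervals and list medians were tested on simulated data for the CAR-like comparison. Apart from genes set to differ, both simulated libraries were Poisson draws from the same pooled profile, as the intervals assume. The figures that follow therefore check the calculation only. They hold no variation between mice, libraries or cells and give no rate of false calls for the real libraries. Over 13106 genes the interval held the true ratio in 95.2%, and 0.488% of 12908 unchanged genes were counted as higher or lower. Of genes set to 1.25, 1.5, 2 and 4-fold (50, 49, 49 and 50 genes), 4.0%, 42.9%, 100% and 100% were counted in the right direction. Random lists fell beyond the outer percentiles in 3.0% of draws, and a list raised 2-fold had a median of 0.97. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.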

Results

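Single-cell transcriptomes were collected from marrow stromal cells that had expressed Adipoq, the gene of the fat-derived hormone adiponectin, which marrow stromal cells also transcribe. Male mice carried Adipoq-CreERT2, a tamoxifen-inducible recombinase, and Ai9, a Cre-dependent tdTomato reporter that stays on once recombined. They received tamoxifen for 3 days at 8 weeks of age. Bright tdTomato-positive cells were sorted from digested endosteal bone of femur and tibia 24 h later (pulse) or 4 weeks later (chase), so the chase mice were also older. The series used 4 mice, and the number behind each library is not given in the sources used here. The sorted cells made up 0.01% of all cells in the pulse sample and 0.29% in the chase sample. Each group has 1 library. No group value and no difference between the groups has a replicate check, no test between the groups was possible, and every interval covers counting error only. Comparisons of cell classes inside a library were made in both libraries, which differ in harvest time. The pulse table held 10608 barcodes with 89009901 UMIs (median 7067.5 UMIs and 2602 genes per barcode). The chase table held 10046 barcodes with 82939659 UMIs (median 6592 UMIs and 2409 genes). After filtering and removal of doublets, 9212 pulse and 8335 chase cells were kept, with median depths of 7772.5 and 7489 UMIs.

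The series set out to identify marrow progenitors with both adipogenic and osteogenic features, and the first comparison asked which cell classes the libraries held. Stromal cells were mainly CAR-like cells, the Cxcl12-abundant reticular cells that maintain blood stem cells. Most were adipogenic CAR-like, marked by Adipoq, Lepr, Cxcl12 and Kitl, and fewer were osteogenic CAR-like, marked by Alpl, Wif1 and Spp1. Runx2, on the same marker list, differed less between these classes. It stood at 335 CPM in osteogenic against 249 in adipogenic CAR-like cells of the pulse library, and at 421 against 245 in the chase library. The osteogenic share of CAR-like cells was lower in the chase library, and osteoblast-like and osteocyte-like cells were found beside them. Osteogenic CAR-like cells numbered 938 of 4414 CAR-like cells in the pulse library, or 21.3% (95% exact interval 20.1 to 22.5). In the chase library they numbered 569 of 4135, or 13.8% (12.7 to 14.8), a ratio of 0.648 (0.582 to 0.719). Adipogenic CAR-like cells numbered 3476 and 3566, or 71.1% and 79.9% of stromal cells. Osteoblast-like cells, with osteocalcin and type I collagen, made up 7.90% (7.16 to 8.69) of stromal cells in the pulse library (386 cells) and 6.99% (6.26 to 7.78) in the chase library (312 cells), with a ratio of 0.885 whose interval (0.760 to 1.03) includes 1. Osteocyte-like cells formed 1 cluster with 88 pulse and 15 chase cells, or 1.80% (1.45 to 2.21) and 0.336% (0.188 to 0.554) of stromal cells. All stromal classes together came to 53.1% and 53.5% of kept cells.

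Blood-like cells made up 36.0% (35.0 to 37.0) of kept pulse cells and 30.6% (29.6 to 31.6) of kept chase cells, although the sort was for the stromal reporter. Monocyte or macrophage-like cells were the most frequent, at 15.3% and 15.1%. B cell-like cells were 5.72% of the pulse and 1.87% of the chase library, a ratio of 0.327 (0.272 to 0.392). T or NK-like cells were 5.58% and 4.14%, and neutrophil-like cells 6.57% and 5.23%. Endothelial-like cells were 4.02% of each library, and pericyte or smooth muscle-like cells numbered 3 and 25. No cluster was named as mature adipocyte-like, chondrocyte-like or fibroblast-like, which sets no limit on single cells of these types inside other clusters. Clusters that the naming rule left without a name held 634 pulse cells (6.88%) and 961 chase cells (11.5%), and that rule was settled after the data were seen. The sorted share differed 29-fold between the samples, and shares of a sorted population follow the gate as well as the tissue.

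The clusters behind a class differed between the libraries. Among adipogenic CAR-like cells, cluster 0 held 2528 pulse and 91 chase cells and cluster 1 held 131 and 2485. Cluster 20, also adipogenic CAR-like, held 30 and 181 cells and was led by the interferon-induced genes Cxcl10, Cxcl9 and Ifit3. When cells were clustered without the 1790 genes that differed between the libraries in CAR-like cells, a setting chosen after the data were seen, the osteogenic ratio was 0.711. With the libraries clustered separately and an earlier form of the naming rule it was 4.96; in that setting a pulse cluster that also carried pericyte markers was left unnamed. At a clustering resolution of 0.5 the osteoblast-like ratio was 1.30, and with the libraries clustered separately the chase library had no osteocyte-like cluster. Under the first form of the naming rule neither library had one.

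**Figure D1:**
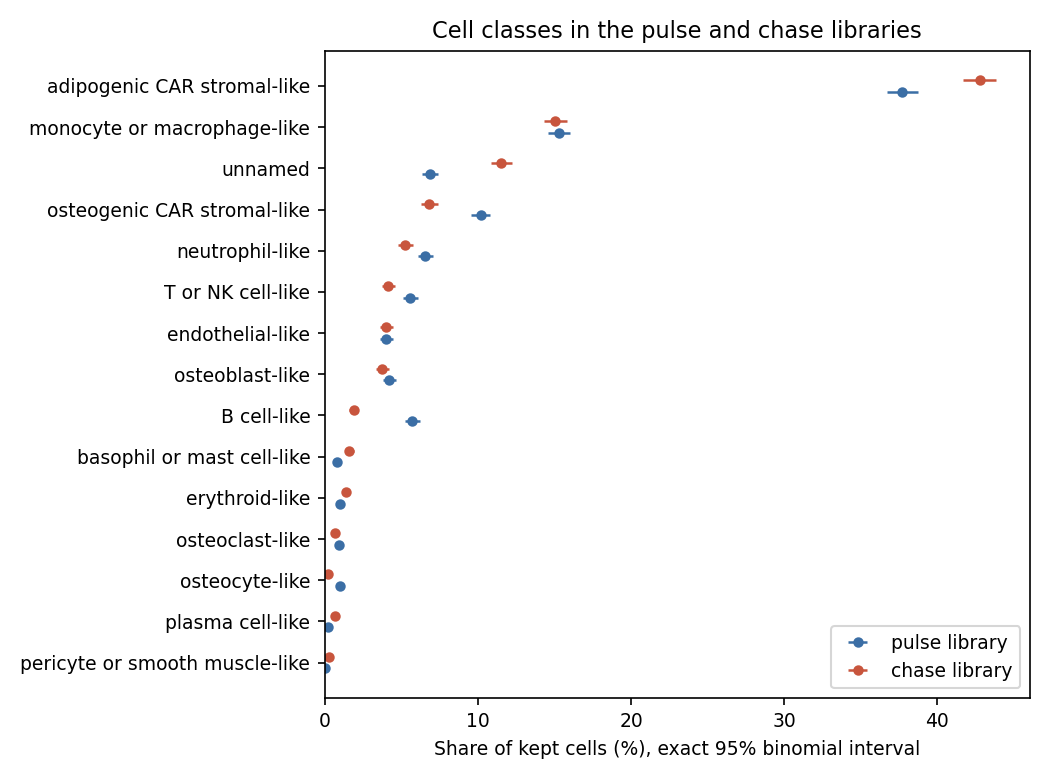
Share of kept cells in each class (horizontal axis, percent) in the pulse (blue) and chase (red) libraries; points are shares and bars are exact 95% binomial intervals. Osteogenic CAR-like and B cell-like shares were lower in the chase library, while the adipogenic CAR-like share was higher.

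The next comparison asked how many stromal cells carried transcripts of both lineages. Adipoq and Alpl, the gene of tissue-nonspecific alkaline phosphatase, which is needed for bone mineralization, were found together in stromal cells of both libraries. Cells with both were most frequent among osteogenic CAR-like cells, and within each CAR-like class the pair occurred about as often as the product of the single shares. Every cell was thinned to 2000 UMIs, which left out 194 pulse and 284 chase stromal cells that were shallower. Adipoq was then seen in 74.6% and 78.8% of stromal cells, Alpl in 24.4% and 24.6%, and both in 12.2% (11.3 to 13.2) and 13.6% (12.6 to 14.7). The product of the single shares was 18.2% and 19.4%. Blood-like cells, which should lack Adipoq, had a UMI of both in 0.448% and 0.532%, of Adipoq in 8.38% and 8.83%, and of Alpl in 1.97% and 1.68%. Whether some blood-like cells express Alpl themselves was not examined, so their Alpl share is not a clean background. Median depths before thinning were 8721 and 7174 UMIs in stromal cells and 6164 and 8946 in blood-like cells, of which 418 and 107 shallower ones were left out. Shallower cells left out numbered 132 and 251 among adipogenic CAR-like, 57 and 25 among osteogenic CAR-like and 5 and 8 among osteoblast-like cells.

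In adipogenic CAR-like cells the pair was seen in 8.79% (7.85 to 9.80) of pulse and 12.1% (11.03 to 13.3) of chase cells, at 0.984 and 0.996 times the product. In osteogenic CAR-like cells it was seen in 31.7% (28.6 to 34.9) and 28.9% (25.1 to 32.9), at 0.968 and 0.969 times the product. Adipoq was seen in 49.3% and 39.5% of osteogenic CAR-like cells and Alpl in 66.4% and 75.4%. Osteoblast-like cells had Adipoq in 6.04% and 4.28%, at or below the blood-like share, which reads as background. Without thinning, the stromal share with both was 31.4% and 31.2% against 2.35% and 2.74% in blood-like cells. The chase-to-pulse ratio of 1.12 after thinning was 0.991 without thinning and 0.978 when at least 2 UMIs of each gene were asked for. Transcripts of osteocalcin, a bone matrix protein made by osteoblasts, were seen in 40.1% (38.7 to 41.5) and 32.4% (31.0 to 33.9) of stromal cells, but also in 35.8% and 22.8% of blood-like cells. In osteoblast-like cells osteocalcin was seen in 97.9% and 99.0%, while the 28.9% and 21.5% in adipogenic CAR-like cells lay below the blood-like shares and read as background. In osteogenic CAR-like cells osteocalcin was seen in 55.1% and 62.9%. Unthinned, osteocalcin was seen in 75.0% and 59.2% of stromal cells and in 67.5% and 59.99% of blood-like cells.

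Osteogenic CAR-like cells were then compared with adipogenic CAR-like cells inside each library, leaving out the marker genes of these classes. Markers of osteoblast-like and osteocyte-like cells, among them Dmp1 and Col1a1, also entered the naming but stayed in the lists. The clusters were formed on variable genes of the same data, so the medians and percentiles here describe the classes and test nothing. Osteogenic CAR-like cells had more transcripts of bone matrix, collagen and cell cycle genes in both libraries. They had fewer of lipid, immediate early, interferon and inflammatory genes. Signs of RNA quality differed with the class. Mitochondrial genes came to 43826 CPM in osteogenic against 32492 in adipogenic CAR-like cells of the pulse library, and to 51751 against 32938 in the chase library. Ribosomal protein genes came to 124719 against 85751 and 101803 against 69269. Neutrophil genes came to 845 against 434 in the pulse but 385 against 452 in the chase library. Of the mineralization list, 10 of 14 measured members were higher and 1 lower in the pulse library, with a median log2 ratio of 2.29 above all 10000 random lists of matched expression, and 10 of 13 were higher in the chase library with a median of 2.69. Dmp1, a matrix protein of osteocytes, was 75.3-fold and 112-fold higher, and Omd (osteomodulin) 14.5-fold and 11.6-fold. The osteogenic list had medians of 0.87 and 0.99, with 7 of 13 members higher in each library, among them Col1a1 (7.44 and 8.10-fold) and the transcription factor gene Mef2c (4.84 and 9.82-fold). The collagen list had medians of 0.63 and 0.70, with 9 of 15 higher in each and 0 and 3 lower, and Col6a3 was 16.5-fold and 19.4-fold higher. Medians of the S phase and mitosis list were 3.61 and 2.11, with 26 of 28 and 21 of 27 members higher, such as Top2a (23.8 and 10.9-fold). Cluster 33, which is led by the mitotic genes Ckap2 and Anln and was named osteogenic CAR-like, held 59 pulse and 15 chase cells. With the libraries clustered separately, the pulse median of this list was 0.83.

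The adipogenic and lipid list was lower in osteogenic CAR-like cells, with medians of −1.01 and −0.69 and 11 of 19 members lower in each library. The pulse median was −0.37 with doublets kept. Fabp4, a fatty acid carrier, was 9.54 and 14.5-fold lower. Niche factors, which serve blood stem cells, had medians of −0.94 and −0.51, with 8 and 7 of 15 members lower. Il34, a ligand of the CSF1 receptor, was 4.11 and 6.70-fold lower, while Ptn (pleiotrophin) was 6.56 and 8.15-fold higher. Immediate early genes, which are switched on within minutes of stimulation or handling, had medians of −1.35 and −1.25 with 21 of 23 members lower in each library. Interferon response genes had medians of −0.68 and −0.56 (14 and 12 of 24 lower), and inflammatory genes −1.06 and −0.99 (16 and 15 of 25 lower, 5 and 3 higher), with Cxcl10 8.81 and 15.7-fold lower. Cholesterol synthesis genes had medians of 0.53 and 0.46 (10 of 22 and 7 of 23 higher).

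The remaining lists follow. Matrix remodelling enzymes had medians of 0.01 and 0.21 (6 and 7 of 20 members higher, 7 and 6 lower), with Mmp9 8.91 and 41.4-fold higher. The Wnt list had medians of −0.09 and −0.18 and a pulse mean of 0.16, of the opposite sign. BMP and TGF-beta genes had medians of −0.16 and −0.12 (10 and 9 of 29 lower), although Bmp3 was 12.95 and 30.8-fold higher. Notch genes had medians of −0.23 and −0.60 (2 and 6 of 11 lower). Heat shock genes had medians of −0.27 and −0.24, hypoxia and glycolysis genes −0.19 in both libraries, and oxidative phosphorylation genes 0.19 and 0.22 with none of 29 past 1.5-fold.

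The main comparison set the chase against the pulse library within all CAR-like cells. Among the genes with the largest ratios, the chemokine genes Cxcl1, Cxcl9, Cxcl10 and Ccl2, the metallothionein gene Mt2 and Zbtb16 had more transcripts in the chase library. The contractile genes Tagln and Myl9, the matrix genes Spon2 and Fbn2, and Tnfsf11 and Socs2 had fewer. Among genes chosen by size, Zbtb16 (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222 on mm10), a glucocorticoid-responsive transcription factor gene, stood at 9.35 and 66.7 CPM (UMIs scaled to the total of the class), a ratio of 7.14 (6.37 to 8.02). Its rise was not particular to CAR-like cells. Zbtb16 was also 6.59-fold higher in chase osteoblast-like, 10.3-fold in endothelial-like, 4.76-fold in neutrophil-like and 1.99-fold in monocyte or macrophage-like cells. Counts were low there, and T or NK-like cells had 1 and 26 UMIs and B cell-like cells 1 and 0. In chase neutrophil-like cells Zbtb16 stood at 5.12 CPM and Adipoq at 141, against 75.6 and 2084 in adipogenic CAR-like cells. RNA carried over from CAR-like cells could account for that neutrophil-like value. In chase osteoblast-like cells Zbtb16 stood at 12.3 CPM with Adipoq at only 30.8, above what such RNA would bring. Carry-over was not separated in the other classes. Serpina3n, an acute phase protease inhibitor, stood at 16.2 and 107 CPM, a ratio of 6.57 (6.02 to 7.18). Fmo2 (ENSMUSG00000040170, chromosome 1, 162874317 to 162898726), a flavin monooxygenase gene, stood at 52.0 and 329 CPM, a ratio of 6.34 (6.03 to 6.65). The chemokine genes Cxcl1, Cxcl10, Ccl2 and Cxcl9 had ratios of 5.55, 4.85, 4.06 and 3.60. The clock output gene Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) stood at 24.3 and 104 CPM, a ratio of 4.29 (3.98 to 4.62). Metallothionein Mt2, which binds zinc, was 4.18-fold higher (123 and 515 CPM), St6galnac2 (ENSMUSG00000057286) 5.01-fold and Angptl1 4.90-fold. Igha, an immunoglobulin heavy chain gene, had the highest ratio among genes with at least 50 CPM, at 8.63 (7.60 to 9.83, 7.28 and 62.8 CPM). It was also between 6.04 and 12.6-fold higher in the B, T or NK, monocyte or macrophage, neutrophil, endothelial and osteoblast-like cells of the chase library.

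Lower in the chase library were Sftpa1 (ENSMUSG00000021789, chromosome 14, 41131782 to 41136452), a surfactant protein gene, at 80.1 and 5.62 CPM and 14.25-fold (12.2 to 16.8). The matrix gene Spon2 (ENSMUSG00000037379, chromosome 5, 33198184 to 33218455) was 9.46-fold lower (8.54 to 10.5), at 131 and 13.8 CPM. Tagln and Myl9, genes of the contractile apparatus, were 7.14 and 3.22-fold lower. Tnfsf11 (ENSMUSG00000022015, chromosome 14, 78277445 to 78308043), which encodes the osteoclast-inducing cytokine RANKL, stood at 284 and 82.1 CPM and was 3.46-fold lower (3.31 to 3.62). Socs2, a cytokine signalling inhibitor, was 3.94-fold lower and Il1rn, the interleukin 1 receptor antagonist gene, 3.13-fold, at 766 and 245 CPM. Rbp4, the retinol carrier, was 4.32-fold lower, Tmem86a 4.11-fold, Omd 3.52-fold, Anxa3 3.11-fold and the fibrillin gene Fbn2 3.02-fold.

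Genes named in advance for their role follow. The genes above were picked for extreme ratios, so the sizes of the differences are not compared. Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028) stood at 1665 and 1809 CPM, a ratio of 1.09 (1.07 to 1.10). The niche genes Lepr, Kitl and Cxcl12 had ratios of 1.62, 1.57 and 1.26, and the Wnt inhibitor gene Wif1 1.66. Lipoprotein lipase (Lpl) was lower at 0.580, and Pparg, the master regulator of fat cell formation, at 0.649. Cebpa had a ratio of 1.14, Alpl 1.04, Runx2 1.02 and Sp7 0.846. Spp1 (osteopontin) had a ratio of 0.842 and Col1a1 0.648. Bglap (osteocalcin) had a ratio of 0.872, and its log2 ratio turned from −0.20 to 0.79 when doublets were removed at the loading rate. The tdTomato transcript had a ratio of 0.972.

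Adipogenic and osteogenic CAR-like cells showed some of these genes to different degrees, and those differences were not tested. Cxcl1 was 5.60-fold higher in the chase library in adipogenic and 2.26-fold in osteogenic CAR-like cells, and Ccl2 4.02 and 1.36-fold. Tnfsf11 was 4.28-fold lower in adipogenic and 1.18-fold lower in osteogenic CAR-like cells. Adipoq had a ratio of 1.06 in adipogenic and 0.699 in osteogenic CAR-like cells, Lepr 1.62 and 0.969, Alpl 1.47 and 1.28, and Spp1 0.648 and 1.24. Bglap had ratios of 0.761 and 1.27 and Col1a1 0.746 and 0.812, so the mix of the classes enters the ratios of all CAR-like cells. Osteocalcin in adipogenic CAR-like cells read as background above, so their Bglap ratio is not read as a difference of these cells. Pulse adipogenic CAR-like cells came mostly from cluster 0 and chase ones from cluster 1, and clusters 2, 19 and 33 held the osteogenic ones (793, 86 and 59 pulse cells against 428, 126 and 15 chase cells).

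**Figure D2:**
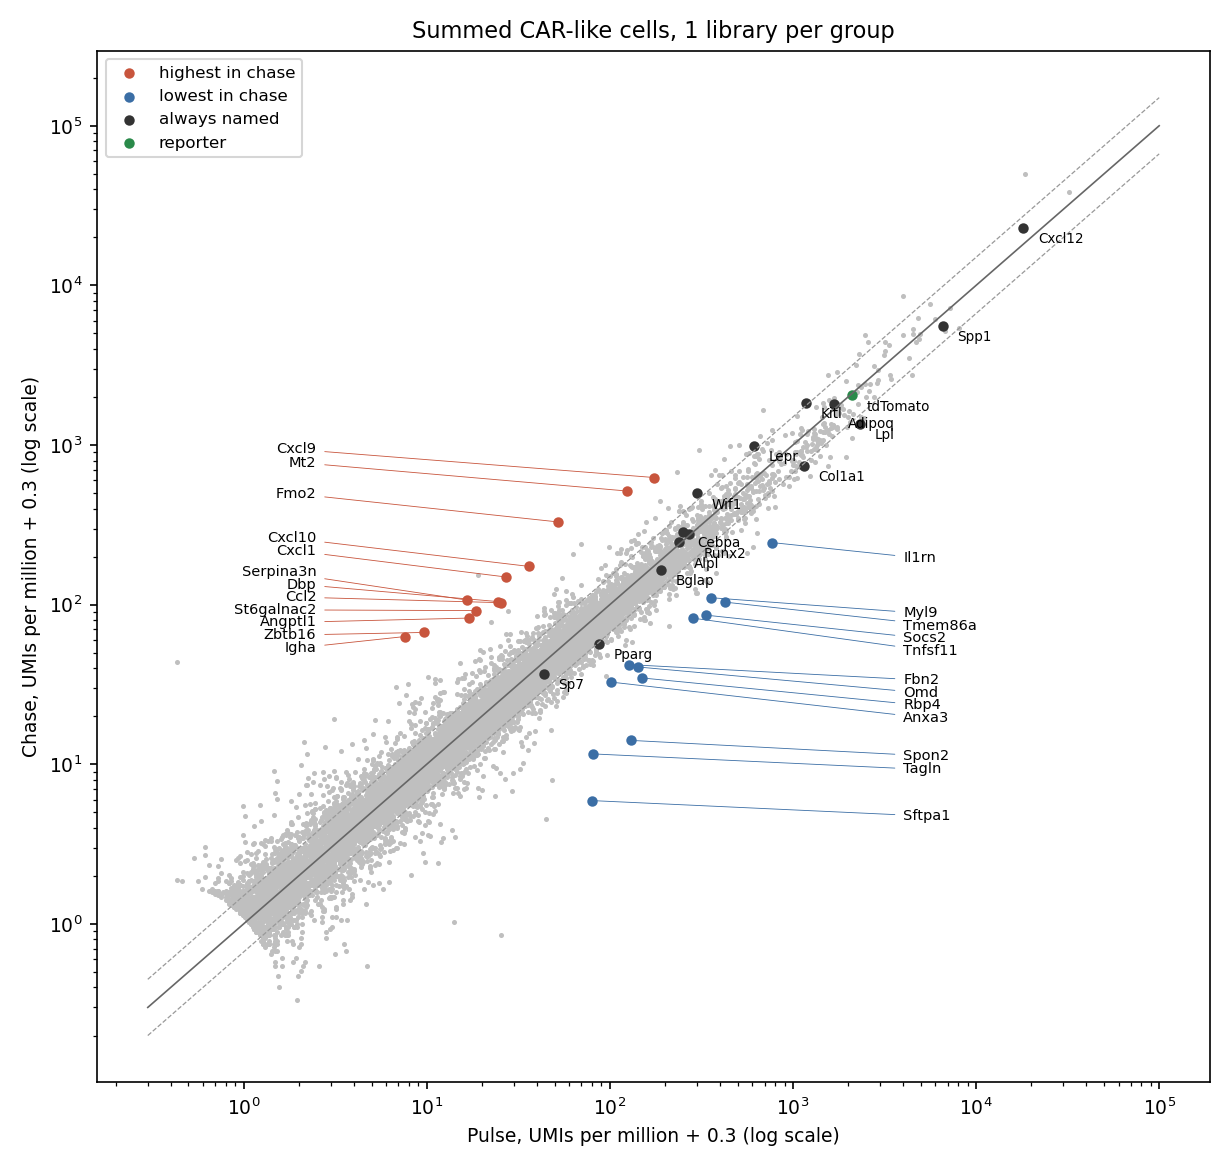
CPM (plus 0.3) of each gene in summed CAR-like cells of the pulse (horizontal) and chase (vertical) libraries, both axes on a log scale; the solid line marks equal levels and the dashed lines 1.5-fold. Red, blue, black and green points mark the genes highest in chase, lowest in chase, always named and the reporter, and Adipoq and tdTomato lie near the line of equal levels.

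By gene list, most inflammatory genes were higher in CAR-like cells of the chase library. Of the collagens 8 were lower and none higher, and immediate early genes had a positive median although most members lay within 1.5-fold. The inflammatory list had a median log2 ratio of 0.95 (0.88 to 1.03), at the 100th percentile of random lists, with 20 of 27 members higher and 3 lower. Immediate early genes had a median of 0.47 (0.45 to 0.47, percentile 100), with 8 of 23 higher and 1 lower, such as Ier3 (2.38-fold) and Socs3 (1.95-fold). Interferon response genes had a median of 0.33 (percentile 100), with 8 of 24 higher and none lower, among them Iigp1 (3.03-fold) and Irf1 (1.95-fold). Cholesterol synthesis genes had a median of 0.34 (percentile 100), with 6 of 23 higher. The Notch list had a median of 0.31 (percentile 99.9), with 2 of 12 higher. Collagens had a median of −0.59 (−0.65 to −0.57, percentile 0), with 8 of 16 lower and none higher, such as Col5a3 (0.407), Col6a2 (0.511) and Col6a3 (0.519). Oxidative phosphorylation genes had a median of −0.35 (percentile 0.025), with 2 of 29 lower.

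The adipogenic and lipid list had a median of 0.17 (0.11 to 0.19, percentile 99.5), with 5 of 25 members higher and 2 lower. Cfd (adipsin) had a ratio of 1.82, Cebpd 1.60 and Lpl 0.580. With doublets removed at the loading rate this median was −0.01, and in adipogenic CAR-like cells alone it was 0.05. The osteogenic list had a median of −0.20 (percentile 12.5), with 1 of 20 higher and 3 lower, Postn (periostin) at 1.72 and the cadherin gene Cdh11 at 0.529. The mineralization list had a median of −0.17 (−0.21 to −0.08, percentile 8.87), with 2 of 14 higher and 3 lower, Phex at 2.14 and Omd at 0.284. This median was 0.02 in adipogenic CAR-like cells alone, with a mean of −0.04, and 0.31 with doublets removed at the loading rate. S phase and mitosis genes had a median of −0.63 (percentile 0), with 16 of 28 lower and Top2a at 0.534, but the median was 0.23 in adipogenic CAR-like cells alone and 0.78 with the libraries clustered separately. In osteogenic CAR-like cells alone the S phase median was −0.73 with 20 of 28 lower, the mineralization median 0.27 (percentile 99.9), the osteogenic median 0.10 (percentile 98.2), the collagen median −0.52, the adipogenic median −0.15 (percentile 15.4) and the inflammatory median 0.61 (11 of 21 higher, 3 lower). In these cells mitochondrial genes came to 43826 and 51751 CPM, ribosomal protein genes to 124719 and 101803, and immediate early genes to 10807 and 14919.

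Niche factors had a median of 0.05 (percentile 93.3), with 4 of 19 higher and 4 lower, Il34 at 1.80 and Angpt1 at 0.598. The niche median was 0.17 in adipogenic CAR-like cells alone, with a mean of −0.02 there, and −0.11 in osteogenic ones. Matrix remodelling enzymes had a median of −0.16 (percentile 25.4), with 1 of 21 higher and 7 lower, among them Adamts9 (0.459), while Mmp9 was 3.51-fold higher. The Wnt list had a median of −0.02 (percentile 58.2; 2 of 24 higher, 5 lower), and Rspo3, a Wnt agonist gene, had a ratio of 0.507. BMP and TGF-beta genes had a median of −0.08 (percentile 48.2; 2 of 29 higher, 2 lower), with the BMP antagonist gene Nog at 2.16 and Tgfb2 at 0.454. Heat shock genes had a median of −0.24 (percentile 8.55), with 2 of 14 lower. Hypoxia and glycolysis genes had a median of −0.22 (percentile 1.84; 4 of 22 higher, 2 lower) and a mean of −0.01.

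**Figure D3:**
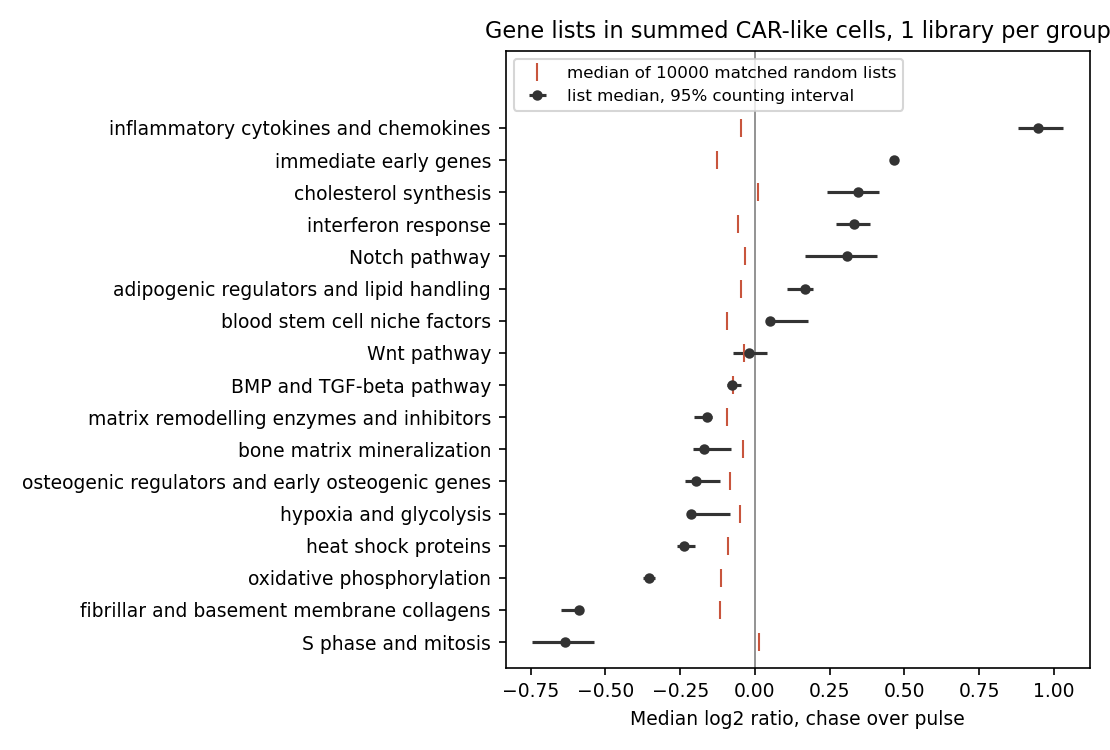
Median log2 chase-to-pulse ratio of each fixed gene list in CAR-like cells, with its 95% counting interval (black), beside the median of 10000 matched random lists (red). The inflammatory list lies highest at 0.95 and the S phase list and the collagens lowest at −0.63 and −0.59.

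The last comparison set the chase against the pulse library within osteoblast-like cells, with 386 pulse and 312 chase cells. The tdTomato reporter and most interferon response genes measured were higher in the chase library, while Mt1, Mt2 and some collagen genes, though not Col1a1, were lower. Osteoblast genes themselves differed little. Mitochondrial genes, a sign of RNA quality, came to 29304 CPM in the pulse and 40994 in the chase osteoblast-like cells. The tdTomato transcript stood at 377 and 1462 CPM, a ratio of 3.88 (3.72 to 4.04), while Adipoq stood at 35.4 and 30.8, a ratio of 0.872 (0.723 to 1.05). With each cell thinned to 8000 UMIs, which left out 42 and 32 shallower cells, 20.3% (16.2 to 25.0) of pulse and 54.6% (48.6 to 60.6) of chase osteoblast-like cells had at least 5 tdTomato UMIs. In neutrophil-like cells that share was 9.78% and 7.54%, and in adipogenic CAR-like cells 80.2% and 86.5%, with 329 and 184 neutrophil-like and 1732 and 2491 adipogenic CAR-like cells left out as shallower. Median depths before thinning were 24506 and 20834.5 UMIs in these osteoblast-like cells and 13002.5 and 13870.5 in the neutrophil-like cells. At least 1 tdTomato UMI was present in 90.7% and 87.1% of the osteoblast-like cells. At the same depth it was present in 56.2% and 51.2% of neutrophil-like and 69.2% and 60.2% of monocyte or macrophage-like cells, so this gate does not mark labelled cells.

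Of 16 measured interferon response genes, 11 were higher in chase osteoblast-like cells and none lower, with a median of 1.08 (0.76 to 1.19, percentile 100). Iigp1 was 2.46-fold and Irf1 1.99-fold higher. Class I histocompatibility genes H2-Q6 and H2-Q7, which share sequence with near-identical neighbours, were 2.90 and 2.74-fold higher. Lars2 and AY036118, whose counts can follow ribosomal or mitochondrial RNA, were 3.20 and 2.81-fold higher, Txnip 2.92-fold and Cdh15 2.43-fold. Cxcl9 was 17.7-fold higher (11.8 to 27.5, 3.04 and 53.6 CPM), but its log2 ratio of 4.12 was 0.29 with doublets removed at the loading rate. Collagens had a median of −0.35 (percentile 0.010), with 7 of 15 lower, such as Col8a1 (0.390) and Col6a3 (0.480). Mt1 was 2.15-fold lower (1540 and 717 CPM) and Mt2 1.91-fold (374 and 195). Ninj1 was 2.75-fold lower, Basp1 2.12-fold, Mamdc2 1.93-fold, Pdgfrl 1.92-fold and Kcnk1 1.83-fold.

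Bglap had a ratio of 0.864 in osteoblast-like cells, Col1a1 0.982, Spp1 0.861, Sp7 0.895, Runx2 1.09, Alpl 1.30 and Wif1 1.48. Lepr, Cxcl12, Kitl and Cebpa had ratios of 1.10, 1.09, 1.23 and 0.882, and Lpl 0.466. Adipoq in osteoblast-like cells read as background above, so RNA carried over from CAR-like cells can enter these ratios. Lpl stood at 49.6 and 23.1 CPM here, against 2887 and 1575 in adipogenic CAR-like cells, where its ratio was 0.546. The Lpl ratio is thus not read as a difference of osteoblast-like cells, and carry-over of the other genes was not separated. At a clustering resolution of 0.5, where osteoblast-like cells made up 12.1% of chase stromal cells, the log2 ratio of Lpl was 0.10, of Adipoq 1.24, of Cxcl12 1.10 and of Cebpa 1.11. The inflammatory list had a median of 0.36 (percentile 99.9; 4 of 16 higher, 2 lower), which was 1.36 at that resolution. S phase and mitosis genes had a median of −0.78 (percentile 0; 12 of 21 lower), but −0.01 with doublets removed at the loading rate and 0.28 at resolution 0.5.

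The remaining lists in osteoblast-like cells had medians between −0.23 and 0.28. Mineralization genes stood at −0.23 (percentile 0.360), with 1 of 14 higher and none lower, and at 0.07 with the libraries clustered separately. Osteogenic genes stood at 0.03 (80.0), with 1 of 20 higher, and adipogenic genes at −0.13 (0.930), with 1 of 16 higher and 1 lower. Niche factors stood at 0.09 (72.5) with a mean of −0.04, matrix remodelling enzymes at −0.08 (17.2) with a mean of 0.01, and BMP and TGF-beta genes at −0.03 (11.6) with a mean of 0.04. The Wnt list stood at 0.21 (95.8), with 3 of 20 higher and 4 lower, Notch at 0.28 (92.4), immediate early genes at 0.13 (99.2) and cholesterol synthesis at 0.14 (63.3). Heat shock genes stood at −0.04 (32.4), hypoxia and glycolysis at −0.07 (7.16) and oxidative phosphorylation at −0.12 (3.84).

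**Figure D4:**
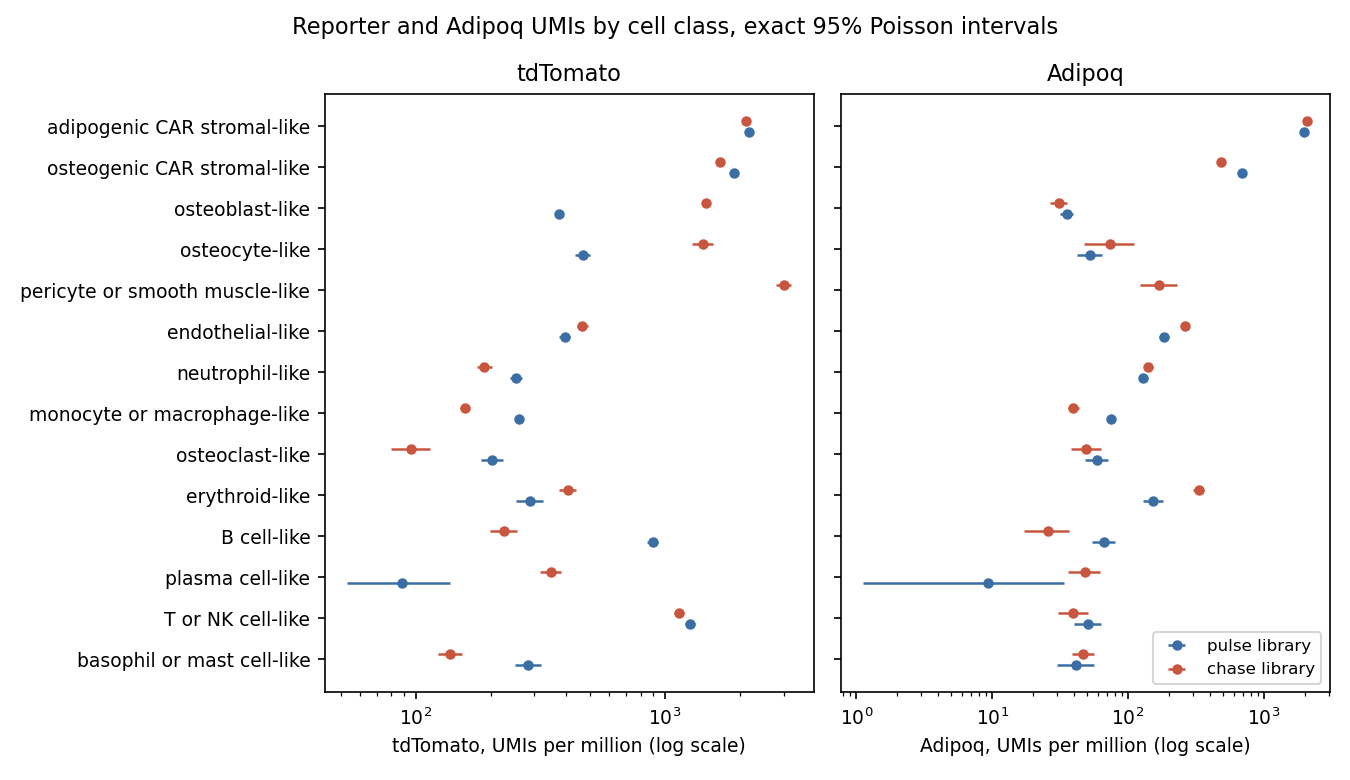
CPM of tdTomato (left) and Adipoq (right) in each class of the pulse (blue) and chase (red) libraries on log scales, with exact 95% Poisson intervals. In osteoblast-like cells tdTomato stood at 377 and 1462 CPM while Adipoq stood at 35.4 and 30.8.

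Transcripts of blood cells and of cell stress were measured in the stromal cells as a check on free RNA, doublets and handling. Stromal cells should lack neutrophil genes such as S100a8 and S100a9, but the neutrophil list also holds Lcn2, a member of the inflammatory list. The neutrophil list came to 533 (525 to 540) and 440 (433 to 448) CPM in CAR-like cells, and to 6270 and 6148 CPM in osteoblast-like cells. In osteogenic CAR-like cells it came to 845 and 385. Other blood lists did not rise alike in osteoblast-like cells, with monocyte genes at 238 and 233 CPM and erythroid genes at 81.7 and 122. Those lists cannot bear on doublets with neutrophils, which would raise the neutrophil list alone. Carried-over neutrophil RNA, such doublets and expression of list members by stromal cells were not separated, so the neutrophil values are not given a source. B cell genes, mostly the immunoglobulin gene Igkc, stood at 34.4 in the pulse and 164 CPM in the chase CAR-like cells, in the same direction as Igha. T or NK genes stood at 3.42 and 3.58, monocyte genes at 117 and 141, and erythroid genes at 150.3 and 195. Plasma cell genes stood at 294 and 246, nearly all of it Sdc1. Osteoclast genes stood at 229 and 193, megakaryocyte genes at 10.3 and 11.3, basophil genes at 1.06 and 3.40, progenitor genes at 105 and 77.0, and endothelial genes at 18.1 in both libraries. Immediate early genes made up 23575 CPM in the pulse and 32464 in the chase CAR-like cells, heat shock genes 6074 and 5263, mitochondrial genes 35222 and 36162, and ribosomal protein genes 95139 and 74845.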

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

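Every test in this part was chosen after the result it weighs had been seen. The metallothionein genes went opposite ways in the 2 stromal classes: Mt2 had a chase-to-pulse ratio of 0.522 (0.488 to 0.558) in osteoblast-like cells and 4.18 in CAR-like cells, and Mt1 0.466 (0.450 to 0.482) and 2.45. They are listed because the direction differed between the classes, and the differences were not tested. A signal outside the comparisons was tdTomato in T or NK-like cells, at 1261 CPM (1205 to 1319) in the pulse library and 1143 (1090 to 1197) in the chase library. The other was BC018473, at 198 CPM (185 to 211; 928 UMIs) in chase neutrophil-like cells. The pulse neutrophil-like cells had 0 UMIs of it, against a limit of 0.537 CPM.

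In osteoblast-like cells tdTomato was 3.88-fold higher in the chase library. More free RNA from CAR-like cells should have brought Adipoq with it, but the Adipoq ratio was 0.872, which argues against that, although at resolution 0.5 the log2 ratio of Adipoq was 1.24. More reporter RNA in every labelled cell is argued against by a ratio of 0.979 in adipogenic CAR-like cells. A different sort gate cannot be told apart from a difference of the cells, since the sorted share differed by a factor of 29 and no unsorted cells were sequenced. Osteoblast-like cells formed by labelled cells during the 4 weeks, which the design names, stay open and untested beside the gate.

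Clock output genes were higher in CAR-like cells of the chase library (median log2 ratio 1.00, 0.94 to 1.10; 7 of 10 higher), among them Dbp (4.29-fold) and Per2 (2.73-fold), while clock activator genes were lower (−0.78, −0.87 to −0.65). A difference of CAR-like cells alone is argued against by medians of 1.38 (0.96 to 1.65) in osteoblast-like and 0.76 (0.57 to 1.14) in endothelial-like cells. Free RNA from CAR-like cells does not account for the endothelial value, since Dbp there was 2.34 times the level that Adipoq predicts (34.5 against 14.8 CPM). A difference between whole libraries, such as the mice or the hour of harvest, stays open, but the classes differed. The output median was only 0.25 (0.08 to 0.43) in monocyte or macrophage-like and 0.36 (−0.07 to 0.74) in neutrophil-like cells. The Dbp ratio was 6.28 in endothelial-like and 2.76 in neutrophil-like cells. It was 1.18 (0.946 to 1.47) in monocyte or macrophage-like, 1.17 (0.691 to 2.01) in T or NK-like and 0.949 (0.452 to 1.92) in B cell-like cells. The ratio of the activator gene Arntl was 0.444 in osteoblast-like, 0.532 in endothelial-like and 0.685 in monocyte or macrophage-like cells. Its interval included 1 in neutrophil-like and T or NK-like cells, and it was 2.07 (1.57 to 2.74) in B cell-like cells. The activator median was −0.03 in endothelial-like cells. The 4 weeks between the harvests stay open and untested.

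In T or NK-like cells tdTomato was 22.5 times the level that Adipoq predicts in the pulse library (56.2 expected CPM) and 28.2 times in the chase library (40.6 expected), which argues against free RNA or doublets from adipogenic CAR-like cells. An excess over that level was not particular to T or NK-like cells. It was 12.2 and 8.63 times in B cell-like, 8.63 and 7.09 in plasma cell-like and 9.68 and 46.4 in osteoblast-like cells. In neutrophil-like cells it was 1.77 and 1.31 times. Free RNA of any make-up spread evenly over cells would give each cell the same number of UMIs, but T or NK-like cells held 1.59 times (1.48 to 1.70) those of neutrophil-like cells in the pulse and 2.55 times (2.35 to 2.76) in the chase library, at median depths of 2609 and 3793 UMIs against 7313 and 9302.5. Other blood-like classes held as many per cell or more, with 4.28 in osteoclast-like and 3.99 in basophil or mast-like against 3.71 in T or NK-like cells in the pulse library, and 7.12 in plasma cell-like and 5.26 in erythroid-like against 5.18 in the chase library, so free RNA taken up unevenly stays open. Cells that passed the sort because they carry the reporter stay open too, and no biological explanation was tested.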

How the results depend on the processing

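Alternatives in this part named as added were chosen after the data were seen. No paired analysis of chase against pulse was possible because each group has 1 library. The CAR-like classes were present in both libraries and were compared inside each, without a paired test. Among the leading results 64 of 90 values stayed within their counting interval, and 10 of the 90 lay on the other side of no difference from the main value. Among all ratios and medians 49 of 1048 lay on the other side: 2 of 351 for genes in CAR-like cells, 9 of 232 for genes in osteoblast-like cells, 6 of 119 for lists in CAR-like cells, 20 of 136 for lists in osteoblast-like cells, 2 of 102 for lists between the CAR-like classes and 10 of 108 for share ratios. One of them is Bglap in CAR-like cells (log2 ratio −0.20, but 0.79 with doublets at the loading rate, added). For genes in CAR-like cells part of the count was fixed in advance. Dropping the low-count filter cannot change the ratio of a gene, and the second naming rule left the CAR-like counts unchanged. TMM and median of ratios shifted the CAR-like log2 ratios by only about −0.00037 and −0.0050. Of the shares per library, 119 of 218 stayed within their interval. Which results lead was settled after the main values were seen. Where values below differ, the cause was not tested. The osteogenic share ratio (0.648) was 0.574 without a filter, 0.558 with doublets kept and 0.831 at resolution 2. With the strict filter, where doublets were removed by a different rule in each library, it was 0.476. It was 4.96 with libraries clustered separately under the second naming rule (added); there an 825-cell pulse cluster was left unnamed. The osteoblast-like share ratio (0.885) was 0.751 with the strict filter, 1.30 at resolution 0.5 and 0.733 in that added setting. The stromal share ratio (1.01) was 1.12 at resolution 0.5 and 1.23 in that setting. The Adipoq and Alpl ratio (1.12) was 0.991 without thinning and 0.978 at 2 UMIs. In osteoblast-like cells (all added) log2 tdTomato (1.96) was 1.88 with TMM and 1.88 with median of ratios, 1.83 with doublets kept and 2.09 with doublets at the loading rate. Lpl turned to 0.10 and S phase genes to 0.28 at resolution 0.5, and mineralization to 0.0731 with libraries clustered separately. In CAR-like cells the adipogenic list (0.17) was 0.0540 in adipogenic clusters alone and −0.00905 with doublets at the loading rate (added). Mineralization (−0.17) was −0.0458 with per-cell means, 0.0230 in adipogenic clusters alone and, both added, 0.31 with doublets at the loading rate and −0.24 with libraries clustered separately. Collagens (−0.59) were −0.69 with per-cell means, −0.69 in adipogenic clusters alone and −0.56 with doublets at the loading rate (added). S phase genes turned to 0.23 in adipogenic clusters alone and to 0.78 with libraries clustered separately (added). Between the CAR-like classes the pulse mineralization median (2.29) was 2.54 with libraries clustered separately (added). The inflammatory list in CAR-like cells ranged from 0.92 to 0.99 over the alternatives, and was 0.61 in osteogenic CAR-like cells alone.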

Other observations

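The lists of clock, glucocorticoid-induced and contractile genes, and the classes looked at here, were chosen after the data were seen. Interferon response genes were also looked at outside the osteoblast-like cells, and in the first 3 classes given here some members were higher in the chase library and none lower. The median log2 ratio was 0.70 in endothelial-like cells (13 of 23 members higher), 0.56 in T or NK-like cells (8 of 17) and 0.54 in monocyte or macrophage-like cells (11 of 24). In neutrophil-like cells it was 0.06 (2 of 18 higher, 2 lower). Glucocorticoid-induced genes, among them Zbtb16, Mt1 and Mt2, had a median of 0.63 in CAR-like cells (6 of 11 higher, 1 lower), 0.32 in osteoblast-like cells (2 higher, 2 lower, with Mt1 and Mt2 among the lower) and 0.28 in endothelial-like cells (5 higher, none lower). In monocyte or macrophage-like cells the median was 0.12 (3 higher, 2 lower) and the mean −0.14.

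Contractile genes were lower in CAR-like cells of the chase library, with a median of −1.61 (6 of 8 lower, 1 higher). The median was −1.64 in monocyte or macrophage-like cells (4 of 4 lower), −0.76 in neutrophil-like and −0.65 in endothelial-like cells. In osteoblast-like cells it was 0.08 with a mean of −0.29. Collagens had a median of −1.65 in monocyte or macrophage-like cells (15 of 16 lower). Stromal transcripts that these cells should lack were lower there too, with ratios of 0.525 for Adipoq (75.5 and 39.6 CPM), 0.661 for Cxcl12 and 0.608 for tdTomato, so the values in monocyte or macrophage-like cells are not read as a difference of those cells. In neutrophil-like cells Adipoq had a ratio of 1.08, Cxcl12 1.12 and tdTomato 0.746, and in endothelial-like cells 1.43, 1.48 and 1.18. These ratios cannot decide whether carried-over RNA enters the contractile medians of neutrophil-like and endothelial-like cells. A steady carry-over would also bring fewer contractile transcripts, since CAR-like cells themselves had fewer in the chase library. Collagens had a median of −0.71 in neutrophil-like cells (8 of 12 lower, 1 higher) and −0.08 in endothelial-like cells (3 of 16 higher, none lower). The cause of the contractile medians was not tested.

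T or NK-like cells fell into cluster 8 (466 pulse and 116 chase cells, with Foxp3 and Ctla4), cluster 24 (2 and 153, with Ifng and Cd40lg) and cluster 27 (46 and 76, with Gzma). Inflammatory genes had a median of 1.01 in this class. The 25 chase pericyte or smooth muscle-like cells held tdTomato at 3001 CPM (2790 to 3225) and Adipoq at 169. Osteocyte-like cells held tdTomato at 469 (437 to 503) in the pulse and 1419 (1290 to 1558) CPM in the chase library. B cell-like cells held 894 and 226 CPM.

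Lars2 was 2.06 to 3.27-fold higher in the chase library in each of the 8 classes examined (the CAR-like classes, osteoblast, endothelial, monocyte or macrophage, neutrophil, T or NK and B cell-like). H2-Q7 was 1.54 to 3.27-fold higher in all of these but B cell-like cells, where its ratio was 0.793. BC018473 had 2 UMIs in pulse and 1155 in chase adipogenic CAR-like cells (ratio 694, 192 to 5735), and 1 and 629 in monocyte or macrophage-like cells.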
